A study of Canis lupus familiaris with 3 samples.

How the data were processed

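Gingiva was cut as a ring around dental implants in beagle dogs that had lost teeth, 1 month after the implants were placed, and its polyadenylated RNA was sequenced. Per the labels' protocols, RNA was extracted with Trizol, libraries were made from 5 ug of total RNA with an RNA integrity number above 7.0, oligo(dT) beads were used to select mRNA, and the strand of origin was kept by marking the other strand with dUTP. The libraries were amplified with 8 PCR cycles and read as pairs of 150 bp. Per the labels, the groups were implants with a smooth neck ring, implants with a microgrooved neck ring, and microgrooved implants combined with CGF, an abbreviation that the labels leave unexplained. Each group had 1 library. How many animals or sites went into a library is not given in the sources used here.

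The deposited table holds 20821 genes with Ensembl dog gene identifiers, their chromosome, start, end, symbol and type, and an FPKM and a count column for each of the 3 libraries. Its columns are marked A, B and C, which match the letters in the sample titles. Per the file headers, the FPKM values are the authors' own: fragments per kilobase of transcript, scaled to the mapped fragments of the library. The deposited counts are whole numbers per gene, as the authors gave them, with no scaling. For the 10419 genes with more than 200 counts in every library, the count divided by the FPKM differed between the microgroove and smooth libraries by a constant factor (SD of the log2 ratio 0.00140). A single factor is therefore the only scaling between that pair. The spread of this ratio was not computed for the library with CGF. This does not show that the factor is the total of the deposited counts. The submitters' processing notes list cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR, with no role or order. The genome build, the annotation release and the treatment of reads that match several places are not given in the sources used here. Coordinates are printed as the table gives them. Genes with close copies (keratins, S100A8, APOBEC3Z1, PLAC8A and ribosomal protein genes among those named) are therefore uncertain at the level of the single locus. In all, 414 genes of the table share their symbol with another, and each locus was counted as a gene of its own.

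FPKM was taken as the main value although counts were present, because with 1 library per group no count test across replicates can be made. Differences are between log2(FPKM + 1) values, a scale that understates the differences of low genes. A gene was called higher or lower when this difference was at least 1, a 2-fold rule, among the 12751 genes with a mean FPKM of at least 1 over the 3 libraries. No p-value, standard error or test between conditions is given. Fold values of single genes are ratios of FPKM. Their 95% intervals are exact (Clopper-Pearson) intervals of 1 gene's counts in a pair of libraries, and shares of counts have Wilson 95% intervals. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only and say nothing of the spread between animals. Where a count was 0, the fold is a lower bound against a floor of 3 counts in that library.

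The rule for the genes named in the text and all gene lists were fixed before the data were examined. SMAD3, JUND and TIMP1 are named in every comparison, since the series title names them. For each comparison the rule also takes the 8 genes with the largest positive and the 8 with the largest negative difference among genes that have a symbol and a mean FPKM of at least 5, leaving out immunoglobulin and T-cell receptor segments, mitochondrial genes and ribosomal protein genes. For each list described, up to 4 measured members with the largest difference are named. Genes named outside this rule are marked as chosen after their values were seen. FOSL2, CXCR2 and TGM1 are also named outside it, each as the only called member that went against its list. There were 39 lists of symbols (signalling pathways, matrix, inflammation, and markers of the epithelial, stromal, vascular, immune and other cell types that a gingival sample can hold) and 1 list of all ribosomal protein genes. A member counted as measured with a mean FPKM of at least 1. With 38 lists having a measured member, 114 list medians were computed, and 2 lists had none. Several symbols of the lists, among them KRT5, KRT14 and MKI67, were not found by symbol and are not analysed here, nor are mitochondrially encoded genes.

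Each list's median difference was placed as a percentile among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. This percentile describes these libraries and is not a test of the conditions. A second percentile, chosen after seeing the data, drew the random lists from joint bins of mean expression and transcript length, and is given where it falls inside the limits below. The report describes TGF-beta and SMAD signalling, the AP-1 factors and the metalloproteinases in every comparison, and any other list whose median lay at or beyond the 1st or 99th percentile, apart from 1 list that is not reported here. A median at or beyond these percentiles was the case for 49 of the 114 medians, against 2.28 for independent random lists, but list members are co-regulated and lists share members, so that number is no measure of chance.

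The alternatives, fixed at the same time, were pseudocounts of 0.1 and 0.01, a mean FPKM of at least 5, no filter, rules of 1.5-fold and 4-fold, the mean in place of the median, and 4 other scalings of the FPKM values. These scalings were an equal sum in every library, median-of-ratios factors, an equal upper quartile, and an equal sum after leaving out the 50 most abundant genes. An alternative chosen after seeing the data subtracted, from each gene's difference, the median difference of its bin among 20 bins of transcript length, with the relative length taken from the ratio of count to FPKM. Another counted protein-coding genes only. The calling step was tested on simulated counts with counting noise only, in which 100 genes were raised 3-fold and 100 lowered 4-fold. For microgroove against smooth, 99% of the raised and 86% of the lowered genes were recovered. For microgroove with CGF against microgroove the shares were 95% and 80%, and for microgroove with CGF against smooth 96% and 83%. Between 3 and 6 unchanged genes were called in each simulation. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.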

Results

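Gingival tissue around dental implants of beagle dogs, a breed in wide use for oral implant models, was profiled by RNA sequencing 1 month after implantation. The neck ring is the part of the implant that passes through the gum. Tissue came from around rings with a smooth surface, rings with microgrooves, and microgrooved rings combined with CGF. The series title names Smad3, JunD and TIMP-1 as a pathway of interest and speaks of immune regulation. There were no replicates (1 library per implant type), so every "higher" and "lower" describes a pair of libraries and none has been tested between conditions. The smooth, microgroove and microgroove with CGF libraries held 44980798, 38082501 and 41854073 counts, on 19122, 18247 and 18854 genes with at least 1 count.

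The microgroove library stood apart from the others in composition. Ribosomal RNA, which oligo(dT) selection is meant to remove, took 2.03% of its counts (Wilson 95% interval 2.03 to 2.04), against 0.359% (0.357 to 0.361) in the smooth library and 0.319% (0.317 to 0.321) in the library with CGF. Most of it came from 1 unnamed locus, ENSCAFG00845018969 on chromosome 8 (936799 to 942348), at 3115 FPKM in the microgroove library, 561 in the smooth and 503 in the library with CGF. Ribosomal protein genes took 15.6% of the microgroove counts, 9.96% of the smooth counts and 10.4% of those with CGF. Differences that involve the microgroove library also followed transcript length. Against smooth, the median difference ran from 0.34 in the shortest of 10 length groups of 11987 protein-coding genes to -0.72 in the longest (Spearman correlation across genes -0.47, genes not being independent replicates). With CGF against microgroove it ran from -0.35 to 0.58 (0.39). With CGF against smooth it ran only from -0.02 to -0.12 (-0.12).

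**Figure D1:**
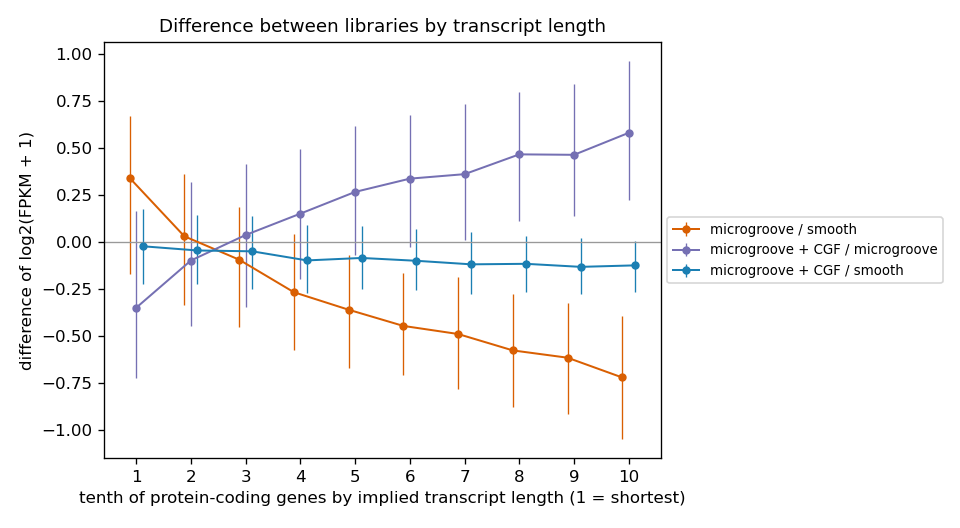
Median difference of log2(FPKM + 1) between libraries (y axis) in 10 equal groups of 11987 protein-coding genes ordered by relative transcript length (x axis, 1 = shortest), with bars from the 25th to the 75th percentile of genes. The comparisons that contain the microgroove library slope, from 0.34 to -0.72 and from -0.35 to 0.58, and microgroove with CGF against smooth stays between -0.02 and -0.13.

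The first comparison, microgroove against smooth, asks how gingiva around a grooved ring differs from that around a smooth one. Of 27 matrix genes 24 were lower in the microgroove library, the largest differences were those of keratins, also lower, and 6 of 14 AP-1 and immediate early factors were higher. KRT24, a keratin of differentiated epithelium, was 62.1-fold lower (95% interval 59.0 to 65.3), at 18.3 FPKM against 1138. KRT76, a keratin of the hard palate and gingiva, was 37.3-fold lower (36.5 to 38.2), at 61.1 against 2279. COL1A1, the main chain of type I collagen, was 4.01-fold lower (3.98 to 4.05), at 357 against 1434. FOS, a subunit of the AP-1 transcription factor, was 5.60-fold higher (5.45 to 5.75), at 324 against 57.8 FPKM.

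Of 12751 genes, 257 were at least 2-fold higher and 1589 at least 2-fold lower in the microgroove library. The median of all genes was itself -0.36, so list medians are given with their value relative to all genes. This split depends on the scaling: with median-of-ratios factors, which put the all-gene median at 0.04, 948 genes were higher and 506 lower. The 257 were all among the 948, and the 506 all among the 1589. Apart from the filter this had to be so, since these factors move every gene's difference the same way. With an equal upper quartile the numbers were 857 and 576. An equal sum, with its relatively smaller pseudocount, gave 196 and 4124 (-0.67). Leaving out the 50 most abundant genes gave 204 and 1944 (-0.44), and removing the length trend 342 and 513.

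Of the genes in the title, SMAD3 (ENSCAFG00845016639, chromosome 30, 31444224 to 31561176), a transducer of TGF-beta signals, was 3.99-fold lower (2.95 to 5.29) in the microgroove library, at 0.80 FPKM and 59 counts against 3.19 FPKM and 268 counts. Its log2 difference of -1.22 was -0.94 with median-of-ratios factors and -0.97 with an equal upper quartile, short of the 2-fold rule. With an equal sum, which also makes the pseudocount relatively smaller, it was -1.74. With pseudocounts of 0.1 and 0.01 it was -1.87 and -1.985. JUND (ENSCAFG00845022784, chromosome 20, 45222673 to 45224061), an AP-1 subunit, was at 96.5 against 51.0 FPKM, 1.89-fold higher (1.81 to 1.97), below the 2-fold rule (0.91), but past it with median-of-ratios factors (1.38). TIMP1 (ENSCAFG00845030572, chromosome X, 41335826 to 41339498), an inhibitor of metalloproteinases, was at 115 against 149.9 FPKM. Its difference of -0.38 became 0.09 with median-of-ratios factors and 0.05 with an equal upper quartile, so it has no direction apart from the scaling.

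The 8 genes with the largest negative difference were KRT24, KRT76, KRT3, SPINK7, PRR9, UOX, KLK10 and SLURP1. KRT3, a keratin of stratified epithelium, was 14.9-fold lower (14.5 to 15.3). SPINK7, a protease inhibitor of squamous epithelium, was 14.9-fold lower (13 to 17.2). PRR9, a gene of the epidermal differentiation complex, had 192 counts in the smooth library and 0 in the microgroove library, at least 55.2-fold lower. KLK10, a kallikrein protease, was 15.9-fold lower (13.4 to 18.8), SLURP1, a secreted regulator of keratinocytes, 11.3-fold lower (8.43 to 15.0), and UOX, urate oxidase, 22.1-fold lower (16.7 to 29.1). The 15 measured suprabasal and cornified keratinocyte markers did not all go this way: 6 were lower, among them CALML5 (0.910 against 14.1 FPKM) and CDSN (0.553 against 7.96), and 3 were higher, TGM1 (286 against 127), TGM3 (67.4 against 16.7) and KRT78 (283 against 94.9). This list is given here, and its members named, after their values were seen; its median of -0.37 (-0.01 relative to all genes) lay at percentile 1.48.

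Of the 10 measured basal keratinocyte markers, 5 were lower and none higher (median -0.98, -0.62 relative to all genes, percentile 0.01, but 9.65 among lists matched for length). TP63, a transcription factor of basal cells, was at 7.94 against 24.9 FPKM, and ITGB4, the hemidesmosome integrin, at 24.6 against 56.7. With the length trend removed, the median was -0.35. Of the 7 measured junctional epithelium markers, the epithelium that seals gum to tooth or implant, 3 were lower and none higher (median -0.93, -0.57 relative to all genes, percentile 0.38). ODAM, a protein of that seal, was 10.8-fold lower (8.14 to 14.3), at 0.955 against 10.3 FPKM, and FDCSP, a secreted peptide of junctional epithelium, 5.08-fold lower (4.96 to 5.19), at 806 against 4089. Among genes with a mean FPKM of at least 5 the list's median was -0.04.

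Lists of connective tissue and vessels had low medians. Of 27 matrix genes, 24 were lower, none was higher and 3 did not meet the 2-fold rule (median -1.49, -1.13 relative to all genes, percentile 0). COL12A1 was 7.22-fold lower (6.74 to 7.75), COL5A1 5.02-fold (4.84 to 5.22) and THBS1, thrombospondin, 5.04-fold (4.69 to 5.43). Of 19 basement membrane and hemidesmosome genes, 12 were lower and none higher (median -1.16, -0.80 relative to all genes, percentile 0), with LAMC1, a laminin chain, at 5.92 against 40.7 FPKM and PLEC, plectin, at 3.88 against 28.2. With the length trend removed this median was -0.48. Of 16 fibroblast markers 8 were lower (median -0.97, -0.60 relative to all genes), of 9 smooth muscle and myofibroblast markers 6 (-1.26, -0.90), of 16 endothelial markers 9 (-1.08, -0.72) and of 20 focal adhesion and integrin genes 9 (-0.91, -0.55). None of these markers was higher, and each of these medians lay at percentile 0. The fibroblast list shares COL1A1, COL1A2, COL3A1, DCN and LUM with the matrix list. Examples were PDGFRB, a receptor of mesenchymal cells, at 21.5 against 54.6 FPKM, MYH11, smooth muscle myosin, at 2.80 against 13.8, KDR, the main VEGF receptor, at 2.80 against 17.4, and TLN1, talin, at 10.3 against 32.4. Many of these transcripts are long, and long transcripts were lower in the microgroove library in general (-0.72 in the longest length group).

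In the TGF-beta and SMAD list, 10 of 24 genes were lower and none higher (median -0.91, -0.55 relative to all genes, percentile 0). Besides SMAD3 these included SKI, a SMAD repressor, at 2.11 against 11.3 FPKM, TGFBR3, a coreceptor, at 0.843 against 5.13, TGFBI, a matrix protein induced by TGF-beta, at 29.9 against 88.3, and CCN2, connective tissue growth factor, at 16.8 against 43.7. The calls of SMAD3 and CCN2 depend on the scaling, their smallest log2 differences under the other scalings being -0.94 and -0.87. With the length trend removed the list's median was -0.42. Of 19 metalloproteinases and inhibitors, 8 were lower and none higher (median -0.93, -0.57 relative to all genes, percentile 0.02). MMP9, a gelatinase of neutrophils, macrophages and osteoclasts, was 7.57-fold lower (6.42 to 8.92), and TIMP3, a matrix-bound inhibitor, 4.05-fold lower (3.87 to 4.23). MMP12, macrophage elastase, was at 2.92 against 9.55 FPKM and ADAMTS2, a procollagen peptidase, at 4.97 against 19.1. Of 5 measured osteoclast genes 3 were lower (median -1.05, -0.69 relative to all genes, percentile 0.5), MMP9, the protease CTSK (33.6 against 77.0 FPKM) and the transcription factor NFATC1 (1.46 against 4.08). This median was -0.37 with a mean FPKM of at least 5 and -0.28 with no filter.

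The AP-1 and immediate early list went the other way, with 6 of 14 higher and 1 lower (median 0.77, 1.14 relative to all genes, percentile 100). IER2 was at 248 against 86.6 FPKM, JUNB at 474 against 174 and ATF3, a stress response factor, at 16.5 against 5.76, whereas the lower one, FOSL2, was at 49.6 against 112. In the list of 14 proinflammatory cytokines and chemokines, 1 was higher and 2 were lower (median 0.41, 0.77 relative to all genes, percentile 100). IL6 was 4.05-fold higher (3.64 to 4.51), at 17.2 against 4.26 FPKM. CXCL12, a stromal chemokine, was at 3.76 against 9.64 and CSF1, a macrophage growth factor, at 10.7 against 22.9. The calcium-binding genes S100A8 and S100A9, abundant in neutrophils and inflamed epithelium, were also higher, S100A9 at 21087 against 6780 FPKM (chosen after their values were seen). The neutrophil list that holds them was mixed. Of its 10 measured markers 3 were higher and 2 lower, MMP9 among the lower (median 0.03, 0.40 relative to all genes, percentile 93.0). Of the 8 measured T cell markers none met the 2-fold rule on the log2(FPKM + 1) scale (median 0.01, 0.37 relative to all genes, percentile 99.1, 97.9 among lists matched for length), CD3D, a T-cell receptor chain, being at 1.92 against 1.07 FPKM and CD4 at 3.02 against 6.79. The sign of that median before centring depends on the scaling (0.28 with median-of-ratios factors, -0.21 with an equal sum). Of 86 ribosomal protein genes, 5 were higher and none lower (median 0.65, 1.01 relative to all genes, percentile 100), with RPS29 at 862 against 404 FPKM and RPL37 at 307 against 139. Short transcripts were higher in the microgroove library in general (0.34 in the shortest length group). With the length trend removed, the AP-1, proinflammatory and ribosomal protein medians were 0.60, 0.44 and 0.47. Among lists matched for length, all of these lists stayed beyond the percentile limits.

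The 8 genes with the largest positive difference were S100P, FOS, a pair of signal recognition particle RNA loci on chromosome 8, CLDN7, C17orf64, CES1 and ELF3. S100P, a calcium-binding protein of epithelia, was 5.60-fold higher (5.29 to 5.94), at 333 against 59.5 FPKM. CLDN7, a tight junction protein, was 5.43-fold higher (5.19 to 5.69), ELF3, an epithelial transcription factor, 4.79-fold (4.55 to 5.03), CES1, a carboxylesterase, 6.43-fold (5.93 to 6.93) and C17orf64 5.34-fold (5.12 to 5.56). The signal recognition particle RNA loci, whose RNA is not polyadenylated, were at 45.5 against 7.49 and 44.3 against 7.43 FPKM, beside the higher ribosomal RNA share of the same library. The other 23 lists lay between percentiles 1.48 and 98.8, with medians from -0.65 to 0.78 relative to all genes.

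The second comparison, microgroove with CGF against microgroove, asks what accompanies CGF on a grooved ring. It shares the microgroove library with the first, so a gene that is out of place in that library appears in both, in opposite directions. Of 27 matrix genes 22 were higher in the library with CGF, as were 8 of 15 suprabasal and cornified keratinocyte markers, and 7 of 14 proinflammatory and 7 of 10 antimicrobial genes were lower. KRT76 was 104-fold higher (101 to 106), at 6329 against 61.1 FPKM. COL1A1 was 10.1-fold higher (10.1 to 10.2), at 3619 against 357. CXCL8, the neutrophil-attracting interleukin 8, was 9.59-fold lower (8.89 to 10.3), at 11.9 against 114. S100A2, an epithelial calcium-binding protein, was 9.35-fold lower (9.24 to 9.47), at 381 against 3563.

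Here 1464 of the 12751 genes were at least 2-fold higher and 422 at least 2-fold lower, with an all-gene median of 0.25. Scaled by median-of-ratios (all-gene median -0.05) the split was 732 higher and 1011 lower, by upper quartile 762 and 982 (-0.03), by an equal sum 3694 and 285 (0.57), and without the length trend 777 and 530. The 732 were all among the 1464, and the 422 all among the 1011, which again follows from the scaling and is no agreement between methods. SMAD3 was 3.19-fold higher (2.34 to 4.28) in the library with CGF, at 2.55 against 0.80 FPKM, with a log2 difference of 0.98 that the pseudocount keeps below the 2-fold rule. JUND, at 114 against 96.5 FPKM, had a difference of 0.23 that became -0.13 with median-of-ratios factors and -0.11 with an equal upper quartile. TIMP1 was at 83.2 against 115 FPKM, 1.38-fold lower (1.32 to 1.44).

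The 8 genes with the largest positive difference were KRT76, KRT24, TGM7, SLURP1, LY6G6C, KRT3, KLK10 and SPINK7. TGM7, a transglutaminase, was 147-fold higher (106 to 201), with 6303 against 41 counts, and LY6G6C, a membrane-anchored protein, 109.6-fold (62.5 to 202), with 1488 against 13. KRT24 was 99-fold higher (94.1 to 104), KRT3 28.0-fold (27.3 to 28.8), KLK10 45.5-fold (38.5 to 53.7), SLURP1 37.9-fold (28.6 to 50.2) and SPINK7 23.6-fold (20.6 to 27.1). Of 15 suprabasal and cornified keratinocyte markers 8 were higher and 1, TGM1, was lower (median 1.32, 1.07 relative to all genes, percentile 100), with CALML5 at 32.6 against 0.910 FPKM and CDSN, a protein of cornified cell junctions, at 18.0 against 0.553. Of 10 basal keratinocyte markers 7 were higher and none lower (median 1.29, 1.03 relative to all genes, percentile 100), TP63 being at 29.9 against 7.94 FPKM and COL17A1, a hemidesmosome collagen, at 91.6 against 33.4.

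Of the 27 matrix genes, 22 were higher and none lower (median 1.9, 1.64 relative to all genes, percentile 100). FMOD, a collagen-binding proteoglycan, was 23.8-fold higher (20.9 to 26.9), COL12A1 11-fold (10.2 to 11.8) and TNC, tenascin, 8.81-fold (8.39 to 9.24). Of 16 fibroblast markers 8 were higher (median 1.02, 0.76 relative to all genes), of 9 smooth muscle and myofibroblast markers 5 (1.21, 0.95), of 19 basement membrane and hemidesmosome genes 9 (0.92, 0.66) and of 20 focal adhesion and integrin genes 5 (0.70, 0.44). None of these was lower, and their percentiles were 100, 100, 100 and 99.8. Among lists matched for length, the last pair fell inside the limits (98.8 and 96.8). COL3A1 was at 2678 against 614 FPKM, NOTCH3, a receptor of vascular smooth muscle, at 29.1 against 6.63, PLEC at 26.2 against 3.88 and TLN1 at 30.6 against 10.3. In the TGF-beta and SMAD list 6 of 24 were higher and none lower (median 0.57, 0.31 relative to all genes, percentile 96.4), with TGFBR3 at 6.30 against 0.843 FPKM and TGFB3 at 8.27 against 1.59. Among 19 metalloproteinases and inhibitors 6 were higher and 2 lower (median 0.46, 0.20 relative to all genes, percentile 92.7). MMP3, stromelysin, was 42.1-fold higher (29.7 to 58.6), with 1625 against 37 counts, TIMP3 was at 55.3 against 10.6 FPKM and MMP2 at 291 against 87.9, and MMP7, an epithelial metalloproteinase, was 4.88-fold lower (4.59 to 5.19). The length trend of this pair of libraries moves with these groups: the longest length group had a median of 0.58.

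Inflammatory and mucosal defence lists had low medians. Of 14 proinflammatory cytokines and chemokines 7 were lower and none higher (median -1.0, -1.26 relative to all genes, percentile 0). IL1A was at 2.75 against 13.8 FPKM, CCL2, a monocyte chemokine, at 5.75 against 20.5 and IL6 at 5.13 against 17.2. With an equal sum the list's median was -0.37. Of 10 antimicrobial and mucosal defence genes 7 were lower and none higher (median -1.73, -1.98 relative to all genes, percentile 0), with SLPI, a secreted protease inhibitor, at 1995 against 7257 FPKM and PI3, elafin, at 49.7 against 242. This median was -1.14 with an equal sum and -0.85 with no filter. WFDC2, a secreted protein of glandular epithelium, had 275 counts in the microgroove library and 0 in the library with CGF. Of 10 neutrophil markers 4 were lower and 1, CXCR2, was higher (median -0.96, -1.21 relative to all genes, percentile 0). The 4 lower were 2 loci of S100A8, S100A9 (6524 against 21087 FPKM) and CSF3R, a receptor of the neutrophil lineage (0.410 against 2.62). S100A8 and S100A9 also belong to the antimicrobial list, so these lists are not separate evidence. Of 17 proliferation genes 1, CDC20, was lower and none higher (median -0.46, -0.72 relative to all genes, percentile 0.01), with CDC20 at 13.3 against 27.8 FPKM and CDK1 at 5.25 against 9.59. Of 86 ribosomal protein genes 5 were lower and none higher (median -0.58, -0.83 relative to all genes, percentile 0.08, 2.11 among lists matched for length). The AP-1 list had 2 of 14 higher and 2 lower (median 0.02, percentile 61.0), a median that was -0.23 with median-of-ratios factors. Its members FOSL2 (124 against 49.6 FPKM) and FOSB (30.9 against 13.2) were higher, and IER2 (118 against 248) and JUNB (232 against 474) lower.

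The 8 genes with the largest negative difference were CXCL17, S100P, PLAC8A, S100A2, CXCL8, AGR2, HSD17B2 and ELF3. CXCL17, a chemokine of mucosal epithelia, was 15.8-fold lower (13.8 to 18.2), at 6.72 against 106 FPKM. S100P was 10.1-fold lower (9.34 to 10.9), PLAC8A 10.1-fold (9.52 to 10.7), AGR2, a disulfide isomerase of secretory epithelium, 17.6-fold (12.5 to 25.5), HSD17B2, a steroid dehydrogenase, 8.97-fold (8.42 to 9.56) and ELF3 8.16-fold (7.65 to 8.71). The 22 lists that the rule does not select had medians from -0.75 to 0.71 relative to all genes, at percentiles from 1.12 to 98.7.

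The third comparison, microgroove with CGF against smooth, leaves out the microgroove library and its length trend. In the library with CGF 5 of 14 AP-1 and immediate early factors and 5 of 15 suprabasal and cornified keratinocyte markers were higher, and 5 of 7 junctional epithelium markers were lower. In every list but the junctional one, most measured members did not meet the 2-fold rule. FOS was 7.33-fold higher (7.14 to 7.52), at 424 against 57.8 FPKM, and COL1A1 2.52-fold higher (2.51 to 2.53), at 3619 against 1434. CXCL17 was 10.5-fold lower (9.19 to 12.1), at 6.72 against 70.9. SPP1, osteopontin, was 7.57-fold lower (7.27 to 7.88), at 39.0 against 295.

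The number of genes at least 2-fold apart was smaller, 165 higher and 192 lower of 12751, with an all-gene median of -0.09. Under the other scalings the median lay between -0.09 and 0.01, with 194 higher and 158 lower by median-of-ratios and 259 and 326 by an equal sum. The FPKM sums of this pair were close (444343 smooth, 441885 with CGF). The equal sum therefore acted here mainly through the relatively smaller pseudocount and the looser filter. Of the genes in the title, JUND was 2.23-fold higher (2.14 to 2.32) in the library with CGF, at 114 against 51.0 FPKM. TIMP1 was 1.80-fold lower (1.73 to 1.88), at 83.2 against 149.9 FPKM, and SMAD3 1.25-fold lower (1.03 to 1.51), at 2.55 against 3.19, neither meeting the 2-fold rule.

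**Figure D2:**
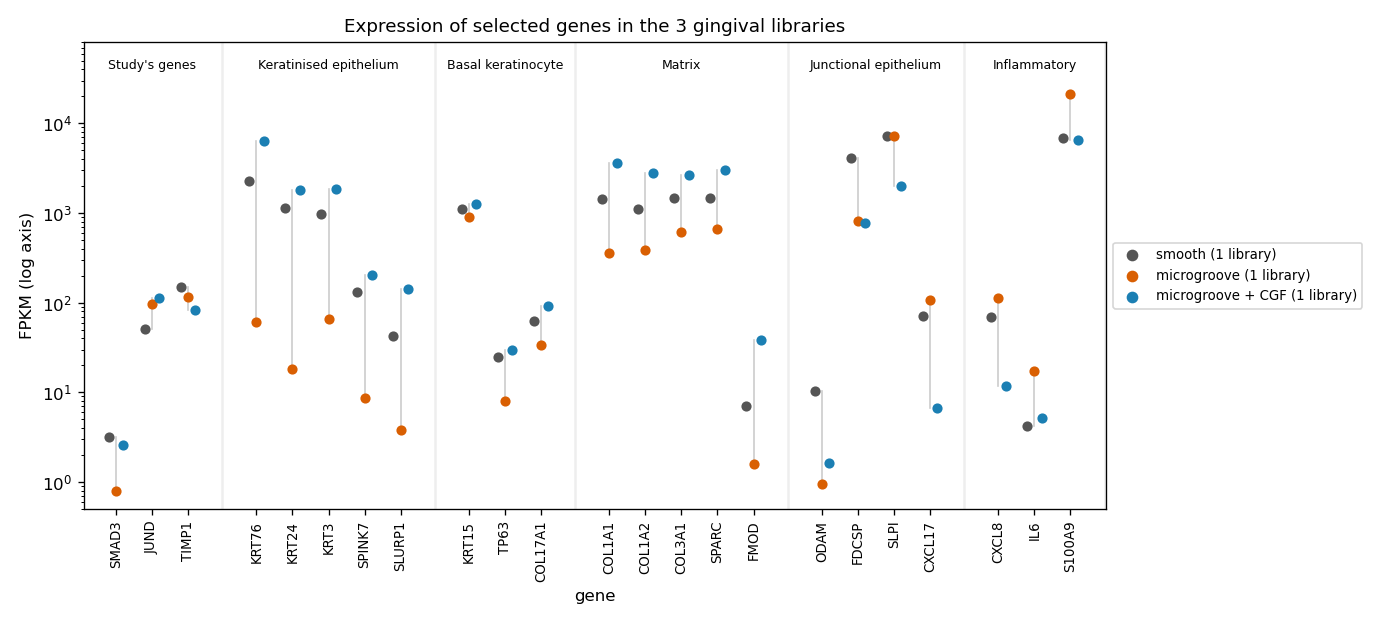
FPKM on a log axis (y axis) of selected genes (x axis) in the smooth (grey), microgroove (orange) and microgroove with CGF (blue) libraries, 1 point per library and a line over their range. The genes were picked for display after their values were seen, and the keratin KRT76, for example, lies at 2279, 61.1 and 6329 FPKM.

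Of the 14 AP-1 and immediate early factors 5 were higher and none lower (median 0.43, 0.52 relative to all genes, percentile 100), with FOSB 6.86-fold higher (6.38 to 7.36) and EGR1 at 69.2 against 31.0 FPKM. Of 15 suprabasal and cornified keratinocyte markers 5 were higher and none lower (median 0.86, 0.95 relative to all genes, percentile 100). KRT76 was 2.78-fold higher (2.77 to 2.79), CNFN, cornifelin, was at 182 against 60.5 FPKM, and TGM3, a transglutaminase of the cornified envelope, at 51.2 against 16.7. None of the 10 basal keratinocyte markers met the 2-fold rule (median 0.23, 0.32 relative to all genes, percentile 99.9), among them COL17A1 at 91.6 against 63.1 FPKM and PKP1 at 433 against 319.5. Of the 27 matrix genes 6 were higher and 1 lower (median 0.33, 0.42 relative to all genes, percentile 100), with FMOD 5.44-fold higher (5.12 to 5.77), COL1A2 at 2777 against 1105 FPKM and THBS1 at 8.48 against 20.7. Of 16 fibroblast markers 3 were higher and 1 lower (median 0.24, 0.32 relative to all genes, percentile 100), the lower one being MFAP5, a microfibril protein, at 2.01 against 7.40 FPKM, beside OGN, a small proteoglycan, at 21.5 against 6.25. Of 86 ribosomal protein genes 1, RPL23A, was higher (median 0.07, 0.16 relative to all genes, percentile 99.8).

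Junctional epithelium markers were lower, 5 of 7, and none was higher (median -1.86, -1.77 relative to all genes, percentile 0). Besides CXCL17, FDCSP was 5.29-fold lower (5.17 to 5.41), at 773 against 4089 FPKM, ODAM 6.37-fold (5.14 to 7.89), at 1.62 against 10.3, and SLPI 3.63-fold (3.60 to 3.67), at 1995 against 7252. Of 10 antimicrobial and mucosal defence genes, a list that also holds SLPI, 3 were lower and none higher (median -0.95, -0.86 relative to all genes, percentile 0). PI3 was at 49.7 against 178 FPKM and LYZ, lysozyme, at 65.8 against 169. With no filter the median was -0.30. Of 14 proinflammatory cytokines and chemokines 4 were lower and none higher (median -0.44, -0.35 relative to all genes, percentile 0), CXCL8 5.84-fold (5.41 to 6.31), CCL2 4.03-fold (3.69 to 4.4), IL1A 3.55-fold (3.13 to 3.98) and CCL20 3.95-fold (3.28 to 4.77).

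Of 17 macrophage and monocyte markers 4 were lower and none higher (median -0.47, -0.38 relative to all genes, percentile 0), with CD68, a lysosomal protein of macrophages, 3.57-fold lower (3.12 to 4.09) and CD163, a scavenger receptor, 2.86-fold (2.63 to 3.12). Of 10 neutrophil markers 3 were lower and none higher (median -0.64, -0.55 relative to all genes, percentile 0.01), with CSF3R 12.4-fold lower (9.60 to 15.7), at 0.410 against 5.08 FPKM, and MMP9, which the metalloproteinase list also holds, 6.95-fold (5.95 to 8.09). Of 19 metalloproteinases and inhibitors 5 were lower and 1 higher (median -0.37, -0.28 relative to all genes, percentile 0). MMP3 was 18.5-fold higher (14.9 to 22.8), at 18.6 against 1.01 FPKM, whereas MMP1, interstitial collagenase, was 10.4-fold lower (8.70 to 12.5) and MMP12 5.85-fold (4.92 to 6.89). Of 11 anti-inflammatory and repair mediators 2 were lower and none higher (median -0.81, -0.72 relative to all genes, percentile 0), TGM2, tissue transglutaminase, at 1.67 against 8.04 FPKM and HMOX1, heme oxygenase, at 12.7 against 32.2. Of 18 interferon-stimulated genes 1 was higher and 1 lower (median -0.54, -0.45 relative to all genes, percentile 0), IFI6 being 6.26-fold higher (5.13 to 7.62) and OASL 2.65-fold lower (2.32 to 3.03).

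None of the 17 proliferation genes met the 2-fold rule (median -0.55, -0.46 relative to all genes, percentile 0), with RRM2, a subunit of ribonucleotide reductase, at 13.6 against 24.4 FPKM. None of the 8 genes of MHC class II presentation met it (median -0.45, -0.36 relative to all genes, percentile 0.08), with DLA-DRA at 243 against 358 FPKM and CD74, the invariant chain, at 316 against 436. None of the 14 hypoxia and glycolysis genes (median -0.31, -0.22 relative to all genes, percentile 0.12) or of the 20 focal adhesion and integrin genes (median -0.23, -0.14 relative to all genes, percentile 0.97, 2.01 among lists matched for length) met it on the log2(FPKM + 1) scale, with HIF1A at 66.9 against 118 FPKM and ITGB6, an epithelial integrin, at 5.77 against 11.7. Of 16 endothelial markers 1, VWF, was lower (median -0.37, -0.28 relative to all genes, percentile 0), at 31.5 against 67.3 FPKM. Of 7 bone and cartilage genes 3 were lower and none higher (median -0.52, -0.43 relative to all genes, percentile 0.17), SPP1, COMP at 0.844 against 3.54 FPKM and ALPL, alkaline phosphatase, at 3.95 against 10.9. With a mean FPKM of at least 5 the median was -1.26. In the TGF-beta and SMAD list 1 of 24, CCN2, was lower and none higher (median -0.15, -0.06 relative to all genes, percentile 19.5), at 18.7 against 43.7 FPKM.

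The 8 genes with the largest positive difference were MMP3, FOS, FOSB, LYPD2, FMOD, IFI6, TGM7 and FAM180B. LYPD2 was 5.64-fold higher (5.14 to 6.18), TGM7 4.95-fold (4.67 to 5.25) and FAM180B 5.88-fold (4.83 to 7.13). The 8 with the largest negative difference were GLNA2, CXCL17, 2 loci of APOBEC3Z1, SPP1, UAP1, MMP1 and CXCL6. GLNA2 was 17.4-fold lower (15.2 to 19.6), at 2.21 against 38.4 FPKM, and UAP1, an enzyme of amino sugar synthesis, 13.7-fold (12.3 to 15.2). CXCL6, a neutrophil chemokine, was 6.62-fold lower (6.40 to 6.85), at 47.9 against 317. The APOBEC3Z1 loci, antiviral deaminase genes on chromosome 10, were 8.61-fold (7.98 to 9.30) and 7.58-fold lower (6.96 to 8.24), and as close copies they can share reads. The 16 lists that the rule does not select had medians from -0.83 to 0.22 relative to all genes, at percentiles from 1.41 to 97.5.

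**Figure D3:**
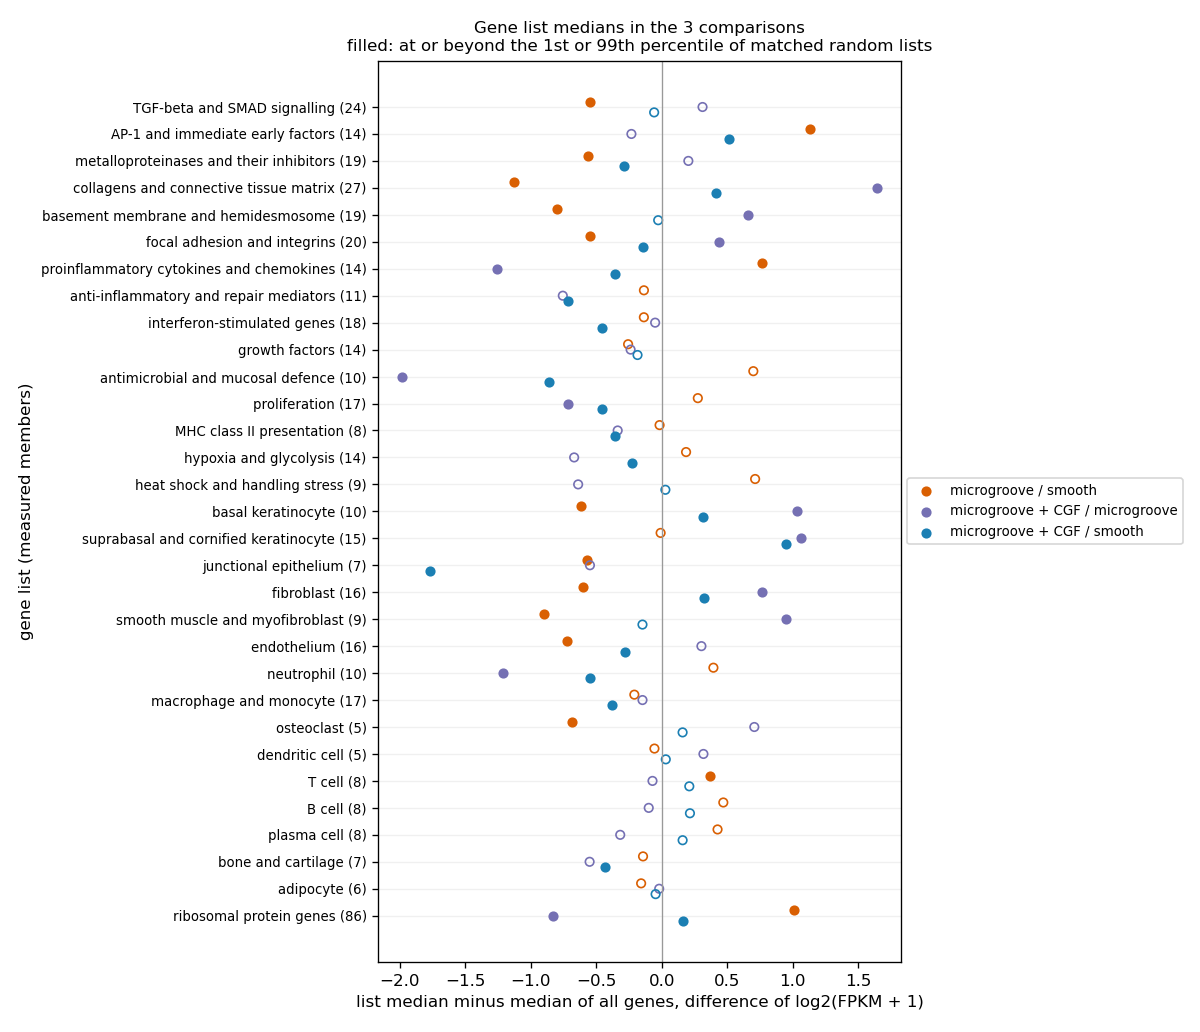
Median difference of log2(FPKM + 1) of each reported gene list with at least 5 measured members (number in brackets), minus the median of all genes (x axis), for microgroove against smooth (orange), microgroove with CGF against microgroove (purple) and microgroove with CGF against smooth (blue). Filled points lie at or beyond the 1st or 99th percentile of matched random lists; matrix genes are at -1.13, 1.64 and 0.42, and the comparisons share libraries.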

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

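The 6 counts of genes, 53 list medians and 247 single-gene differences that the naming rule selects were recomputed under each alternative that applies to them. A list median or a gene was taken as kept when it moved by less than 1.5-fold on the log2 scale, and a count when it stayed within 1.5 times. A turned sign was counted apart for list medians and for genes that met the 2-fold rule. Other genes whose sign turned within the limit count as kept, such as TIMP1 in microgroove against smooth (-0.38, 0.09 with median-of-ratios factors). Of the single-gene values under these alternatives 2080 were kept, 99 moved and none that met the 2-fold rule turned its sign. Much of this tally was fixed in advance. The filters cannot change a single gene's difference, yet they gave 247 and 203 kept values. Median-of-ratios, the upper quartile and leaving out the 50 most abundant genes shift all genes the same way, by less than the limit. Each of these scalings therefore kept all 247, so the tally is no measure of robustness. Of the list medians 507 were kept, 15 moved and 8 turned their sign, and of the counts 41 were kept and 37 moved. Removing the length trend and counting protein-coding genes only were chosen after seeing the data, and the others were planned. Except where an alternative's own construction shows it (a stricter rule or fewer genes), the cause was not tested. With 1 library per group, no library can be left out of its group. Dropping the microgroove library leaves only microgroove with CGF against smooth (165 higher, 192 lower). Counting all loci moved nothing because the table holds no unannotated loci, leaving out 1 of several columns per sample did not apply, and no paired analysis was possible because each group has 1 library.

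For microgroove against smooth, the number of higher genes (257) was 948 with median-of-ratios factors, 857 with an equal upper quartile, 33 under a 4-fold rule and 883 under a 1.5-fold rule. The number of lower genes (1589) was 506 and 576 under those scalings, 4124 with an equal sum, 69 and 4348 under the 4-fold and 1.5-fold rules, 2698 and 2852 with pseudocounts of 0.1 and 0.01, 957 with a mean FPKM of at least 5, and 513 without the length trend. For microgroove with CGF against microgroove, the higher genes (1464) numbered 732 and 762 by median-of-ratios and upper quartile, 3694 with an equal sum, 125 and 3725 under the 4-fold and 1.5-fold rules, 2422 and 2541 with pseudocounts of 0.1 and 0.01, 879 with a mean FPKM of at least 5, and 777 without the length trend. The lower genes (422) numbered 1011 and 982 under the first 2 scalings, and 57 and 1238 under the 4-fold and 1.5-fold rules. For microgroove with CGF against smooth, the higher genes (165) numbered 25 and 461 under those rules, 261 with a pseudocount of 0.01, 103 with a mean FPKM of at least 5, and 259 with an equal sum. The lower genes (192) numbered 26 and 783, 361 and 395 with pseudocounts of 0.1 and 0.01, 114 with a mean FPKM of at least 5, and 326 with an equal sum.

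Both list medians that turned their sign lay near 0. AP-1 factors with CGF against microgroove (0.02) were at -0.23 by median-of-ratios, -0.22 by upper quartile, -0.10 with a mean FPKM of at least 5 and -0.061 without the length trend. T cell markers in microgroove against smooth (0.01) were at -0.34 with a mean FPKM of at least 5, -0.21 with an equal sum, -0.052 without the 50 most abundant genes in the total, and -0.056 as a mean. Among medians that moved in microgroove against smooth, smooth muscle markers (-1.26) were at -1.87 and -1.99 with pseudocounts of 0.1 and 0.01, junctional epithelium markers (-0.93) at -0.038 with a mean FPKM of at least 5, osteoclast genes (-1.05) at -0.37 with that minimum and -0.28 with none, and basal keratinocyte markers (-0.98) and basement membrane genes (-1.16) at -0.35 and -0.48 without the length trend. With CGF against microgroove, neutrophil markers (-0.96) were at -1.64 and -1.70 with those pseudocounts and -1.73 with a mean FPKM of at least 5, antimicrobial genes (-1.73) at -1.14 with an equal sum and -0.85 with no filter, and proinflammatory genes (-1.0) at -0.37 with an equal sum. With CGF against smooth, bone and cartilage genes (-0.52) were at -1.26 with a mean FPKM of at least 5, and antimicrobial genes (-0.95) at -0.30 with no filter. Depth limits low genes most: a count of 0 allows up to 3 counts of the 44980798, 38082501 and 41854073 in the smooth, microgroove and microgroove with CGF libraries.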

Other observations

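Immunoglobulin constant genes, products of plasma cells and B cells, took 0.149% of the counts of the microgroove library (Wilson 95% interval 0.148 to 0.150), 0.105% (0.104 to 0.106) with CGF and 0.0721% (0.0714 to 0.0729) of the smooth library. JCHAIN, which joins IgA and IgM chains, was at 123.5, 115.5 and 61.3 FPKM in the same order. The plasma cell list, which holds JCHAIN, had no member past the 2-fold rule in any comparison. In microgroove against smooth JCHAIN fell just short of that rule on the log2(FPKM + 1) scale. In microgroove against smooth, 4 of 10 antimicrobial and mucosal defence genes were higher and 1 lower (percentile 82.9), WFDC2 having 275 counts against 14. GADD45B, a stress response gene, was at 90.7 FPKM in the microgroove library, 26 in the smooth and 24.9 with CGF. Of 17 macrophage and monocyte markers 5 were lower in microgroove against smooth (percentile 4.67), with CD163 at 1.35 against 8.66 FPKM and MSR1, a scavenger receptor, at 0.266 against 3.81. These genes were chosen after their values were seen.

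The 3 patterns weighed next were picked from these data, and the tests of them were chosen after the values they rest on had been seen, although the 4 other scalings had been fixed before the data were examined. Each explanation is tested as the whole cause, the bootstrap intervals are over genes and not over animals, and a mixture of partial causes stays open throughout.

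Matrix genes were lower in the microgroove library than in the smooth library (24 of 27, median -1.49). A loss of signal from long transcripts in that library is argued against as the whole cause, since the list kept a median of -0.99 after each gene's length bin was centred (bootstrap 95% interval -1.11 to -0.69). The 4 other scalings do not account for it either, the highest median under them being -1.02. They shift all genes the same way, and none shifts them enough to have removed this difference. Less connective tissue in the sample stays open. It would lower the immune cells that reside there too, and with a pseudocount of 0.01 the length-centred median of T, B, plasma and mast cell markers (0.15) lay 0.95 above that of endothelial and smooth muscle markers (-0.80; interval of the difference 0.62 to 1.41). But 18 of these 28 immune markers had a mean FPKM below 5, too low to decide, and macrophage and monocyte markers were at -0.52 on the same scale. Endothelial and smooth muscle lists were low together, as less connective tissue predicts. The fibroblast list was low too, but it shares COL1A1, COL1A2, COL3A1, DCN and LUM with the matrix list, so it is in part the same pattern. A hypothesis that the implant surface may be linked to lower matrix expression is untested, as are RNA quality and the individual animal, because the surface is represented by 1 library.

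The 8 named genes furthest down in the microgroove library, 3 of them keratins of differentiated epithelium, had a median of -3.69 against smooth. A loss of signal from long transcripts is argued against as the whole cause, since these were not long transcripts: their median percentile of transcript length among all measured genes was 25.8 (bootstrap interval 2.89 to 36.9), and the highest was 42.7. Less epithelium stays open. The median of basal keratinocyte markers lay 2.71 above that of the 8 genes (2.13 to 4.03), but it had to lie above, because the 8 were picked as the lowest. Basal markers were themselves lower (5 of 10, none higher), which goes with less epithelium. But their median of -0.98 was -0.35 with the length trend removed, and lay at percentile 9.65 among lists matched for length. TGM1, TGM3 and KRT78, markers of differentiated cells, were higher. Which zone of the gum, keratinised or not, was cut is a candidate explanation that was not tested, as is the implant surface.

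Junctional epithelium markers were lower in the library with CGF than in the smooth library (5 of 7, median -1.86). The highest median under the 4 other scalings was -1.75. For this pair of libraries the scalings put the all-gene median between -0.09 and 0.01, so none could have moved the list far. Only these scalings are argued against. A smaller share of epithelium is argued against by the basal keratinocyte markers themselves, none of which was lower by the 2-fold rule (median 0.23). Their median lay 2.09 above that of the junctional list (bootstrap interval 0.93 to 2.72). That gap decides nothing by itself: basal markers had to lie above, because the junctional list had the lowest median of this comparison. ODAM and FDCSP were also lower in the microgroove library without CGF (0.955 and 806 FPKM against 10.3 and 4089 in the smooth library), whereas CXCL17 and SLPI were not (106 and 7257 against 70.9 and 7252). Whether CGF, the groove, the zone of gum that was cut, or less inflammation of the seal may account for these markers stays open and was not tested.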
